A study of Homo sapiens with 6 samples.

How the data were processed

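The series measured polyadenylated RNA in HEK293T/17 cells, a human embryonic kidney line, 48 h after transfection with 25 nM siRNA, and protein-bound DNA in untreated cells of the same line. The labels give 2 libraries for siCtrl (a non-targeting siRNA pool), 2 libraries for siSUZ12 (an siRNA pool against SUZ12), 1 EZH2 chromatin immunoprecipitation (ChIP) library and 1 H3K4me2/3 ChIP library. The labels number the RNA libraries as biological replicates 1 and 2.

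The RNA values were made by the authors with TopHat, Bowtie and Cuffdiff on hg19, per the submitters' processing notes, and tool versions are not given in the sources used here. The expression values are RPKM (reads scaled by transcript length and by mapped reads), per the file headers. Each RefSeq transcript has 1 RPKM value per group in the deposited table, and how Cuffdiff combined the 2 libraries of a group is not given in the sources used here; values per replicate were not used here. The deposited fold is the ratio of siSUZ12 RPKM to siCtrl RPKM, per the file headers, and it equalled the quotient of both columns within 0.0129%. A transcript listed at 0 in 1 group has no finite fold, and it is described here as listed at 0. The deposited table also holds a column headed q-value and a significance flag of 1 or 0, the authors' call, per the file headers.

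The deposited column headed q-value was tested on its own values and behaved as an uncorrected p-value. Its median was 0.497, and 3107 transcripts lay below 0.05 while 736 carried the authors' flag. The flag matched a Benjamini-Hochberg limit of 0.05 if between 20633 and 20831 transcripts had been tested, counting each transcript with a value above the highest flagged one in the ranks. Another 89 transcripts at or below the highest flagged value carried no flag, and the highest RPKM among them was 0.380. The calls reported are therefore the authors' flags, and "called" means flagged by the authors. How Cuffdiff was set is not given in the sources used here.

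The table holds 30469 transcripts, of which 26526 are NM and 3943 are NR identifiers, at 16170 distinct loci of the 22 autosomes. Genes of the sex chromosomes were not analysed here for RNA. Symbols were assigned by transcript identifier from the RefSeq gene list of assembly GRCh38.p14, used for names alone (C10orf12 was left out, since that list merges it with another gene); 29505 transcripts (96.8%) matched and 964 did not. Leaving out 402 transcripts of RNAs under 200 bp, the RPKM values of a gene's transcripts were added per group, which gave 17757 genes. Of these, 11759 had a summed RPKM of at least 1 in either group and were tested in lists and classes, and 4835 of them had more than 1 transcript. Gene log2 folds were computed from sums with a pseudocount of 1, which understates the change of low genes. Their median was -0.03 and their SD across genes was 0.13. Transcript coordinates are those of hg19 as the deposited table lists them, without strand.

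Peaks were called by the authors with Bowtie alignments and MACS2, per the submitters' processing notes, with a q-value limit of 0.01 as the names of the deposited peak lists give it. The notes name both hg19 and mm9. The chromosomes and positions of both lists are those of human hg19. The score of each peak is the authors' −log10 q-value, since its lowest values lie where that limit puts them, and it served here to rank and describe peaks within a list. Each list comes from 1 library, not pooled, and no input library was used here. Depth is unknown for all 6 libraries, since the RPKM are model estimates and no read counts were used; intervals on shares of peaks or genes cover counting error alone.

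The planned tests per replicate were replaced by the authors' calls, as the written plan allowed for a table that gives group values alone. Without strand, the planned promoter window was replaced by its written fallback, the whole locus with 1 kb on either side. A gene was placed in 1 of 4 classes by whether that window met an EZH2 peak, an H3K4me2/3 peak, both or neither, by at least 1 bp. The chance overlap of peak sets came from 1000 random placements of the EZH2 peaks with the same widths on the same chromosomes, within the span that either list covers. Shares were compared with Fisher's exact test, two-sided, and shares of 1 list are given with exact (Clopper-Pearson) 95% intervals. Median expression was compared between classes with 100000 permutations, two-sided. Median log2 folds were compared with 10000 permutations of class within deciles of siCtrl expression, two-sided. Genes are not independent replicates, so these tests describe the genes of these libraries and not the spread between cultures.

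The 21 gene lists, and the tests above, were chosen before the data were examined. A list with at least 3 tested genes had its share of called genes compared with the other tested genes by Fisher's exact test, adjusted by Benjamini-Hochberg over the 17 lists so tested. The median log2 fold of each list was placed among the medians of 10000 random lists of the same size matched on expression in 20 bins. For each list, Benjamini-Hochberg was also applied to the column headed q-value, over all transcripts of at least 1 RPKM and adjusted over the list alone.

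Genes were named by a rule with 6 parts. Part 1 took each gene of the PRC2 core and accessory lists. Part 2 took the 10 called transcripts of largest rise and the 10 of largest fall with at least 1 RPKM in both groups; of 431 such calls, 7 without a symbol were left out, 0 short RNAs and 0 read-throughs, which left 424. Part 3 took, for each list with a call, up to 4 called members and up to 2 uncalled members of highest expression. Part 4 took the 5 strongest peaks of each list, part 5 the 5 called genes of largest fold with an EZH2 peak in each direction, and part 6 the 5 HOX genes of highest siCtrl expression. An item that parts 3 and 4 of the rule each take is not reported here. Genes named outside the rule are said to be so where they appear.

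The permutation within expression deciles was tested on simulated data for 1474 genes: 3.3% of simulations without a class effect gave a p below 0.05, and shifts of 0.05 and 0.10 in log2 were recovered as 0.046 and 0.098. The simulated values were independent between genes, with a trend over the same deciles and none over locus length. They check the calculation and not the effect of locus length, whose median was 33.9 kb with EZH2 alone and 11.0 kb with neither. Among random lists of 35 genes drawn from 11759, with simulated values independent between genes, 3% fell outside the central 95% of matched lists. Lists whose genes move together were not simulated, and their percentiles can lie further out than this rate implies. Random placement of 46886 simulated peaks gave a ratio of 0.998 where no relation was planted, and a planted share of 9.72% was recovered as 9.66%. The simulated peaks were drawn evenly over the same spans as the random placements. They therefore check the calculation and not whether even placement suits real peaks.

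Alternatives covered the pseudocount (0.1), the RPKM minimum (none or 5), centring on the median gene, stricter calls, the score and overlap limits of peaks, and the window (5 kb). Others, chosen after the data had been seen, counted peaks at the locus ends alone, restricted genes to those with 1 transcript, took the column headed q-value at face value, matched on locus length and moved peaks locally. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures used matplotlib 3.10.9. Positions relative to exons were not analysed here, since no hg19 annotation was used.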

Results

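RNA from HEK293T/17 cells, an established human embryonic kidney line, was sequenced 48 h after transfection with an siRNA pool against SUZ12 (siSUZ12, 2 libraries) or a non-targeting pool (siCtrl, 2 libraries). Untreated cells gave 1 ChIP library for EZH2 and 1 for H3K4me2/3, the methylation of histone H3 at lysine 4 found at active promoters. SUZ12 and EZH2 are core subunits of Polycomb repressive complex 2 (PRC2), a histone methyltransferase that represses developmental genes. The RNA table gives 1 RPKM value per group for each of 30469 RefSeq transcripts, so expression values carry no spread between replicates, and the calls of change are the authors'. Summed over all transcripts, RPKM came to 599029 in siCtrl and 570345 in siSUZ12. Read depth is unknown.

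The targeted gene comes first. SUZ12 (NM_015355, hg19 chromosome 17, from 30264043) fell from 22.4 RPKM in siCtrl to 5.36 in siSUZ12 in the authors' deposited table, a fold of 0.239 or 4.19-fold lower. RBBP4, a histone-binding subunit of PRC2 and of other chromatin complexes, also fell: the authors' deposited table lists its transcript NM_005610 (chromosome 1, from 33116748) at 42.6 and 29.8 RPKM, a fold of 0.700 (gene sum 0.702). The catalytic subunit EZH2 had 5 transcripts, none of them called in the authors' deposited table, and their sum was 51.9 RPKM in siCtrl and 49.8 in siSUZ12 (fold 0.961). Its most expressed transcript, NM_001203247, was listed at 30.5 and 23.7 RPKM (fold 0.779) in the authors' deposited table, with 0.00773 in the column headed q-value. Each of the other EZH2 transcripts was listed higher in siSUZ12. EED, the subunit that binds methylated histone tails, was listed at a fold of 0.909 from 22.8 RPKM in siCtrl and EZH1, the alternative catalytic subunit, at 9.12 RPKM in both groups, and neither was called in the authors' deposited table. RBBP7 was not analysed here.

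Among the accessory subunits of PRC2, which steer the complex to chromatin, 1 of 6 had a called transcript in the authors' deposited table. MTF2 NM_001164391 rose and was listed at 0 in siCtrl and 3.14 RPKM in siSUZ12, while the sum over MTF2 transcripts of the authors' deposited table had a fold of 0.940. The uncalled genes had gene-sum folds, from the authors' deposited table, of 0.861 for JARID2, 0.877 for AEBP2, 0.922 for PHF1, 1.02 for PHF19 and 1.04 for EPOP (C17orf96). C10orf12 was not analysed here.

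SUZ12 knockdown was next compared over all transcripts, to ask which genes change when the RNA of a PRC2 core subunit is lowered. SUZ12 protein was not analysed here. The largest rises among called transcripts with at least 1 RPKM in both groups were, in the authors' deposited table, PSRC1 (a spindle microtubule protein; NM_032636, 1.89 to 9.94 RPKM, fold 5.26), CYREN (a regulator of DNA end joining; 4.21), RAB34 (a small GTPase; 4.11), CDK10 (a cyclin-dependent kinase; 4.10) and SNHG29 (a small nucleolar RNA host gene; 3.90). They were followed in the authors' deposited table by EIF2B4 (a translation initiation factor subunit; 3.78), ZBTB22 (a zinc finger protein; 3.62), CHEK2 (a DNA damage checkpoint kinase; 3.21), STXBP5 (a syntaxin-binding protein; 3.12) and BRMS1 (a metastasis suppressor; 3.03). The largest falls in the authors' deposited table were CELF1 (an RNA-binding splicing factor; NM_001025596, 6.19 to 1.08 RPKM, fold 0.175), PDCD2 (0.208), SLC52A2 (a riboflavin transporter; 0.211), DCAF8 (a ubiquitin ligase adaptor; 0.218) and SUZ12 itself (0.239). SCRN1 (0.241), ZNF48 (a zinc finger protein; 0.258), ORC1 (the largest subunit of the origin recognition complex; 0.266), TJAP1 (a tight junction protein; 0.274) and APBB1 (a binding partner of the amyloid precursor protein; 0.309) followed in the authors' deposited table.

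Of these 20 genes, SUZ12 had 1 transcript in the table and the others had several. The sums of the other risers lay between 0.868 for ZBTB22 and 1.06 for STXBP5, and those of the other fallers between 0.898 for ZNF48 and 1.13 for TJAP1, in folds computed from the authors' deposited table. In total 736 transcripts (2.42%) were called in the authors' deposited table, 338 higher and 398 lower, and 130 of them were listed at 0 in 1 group. Of the called transcripts, 719 had a gene symbol and were not short RNAs, and these belonged to 616 genes, of which 233 had calls higher alone, 290 lower alone and 93 in both directions. Calls in genes with several transcripts numbered 610, and for 199 of these (32.6%) the gene sum moved the other way; the called transcripts had a median absolute log2 fold of 0.66 and their gene sums of 0.10. Calls in genes with 1 transcript numbered 109, with a median absolute log2 fold of 0.33 and 35 higher against 74 lower. With at least 5 RPKM the calls were 92 higher and 200 lower.

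**Figure D1:**
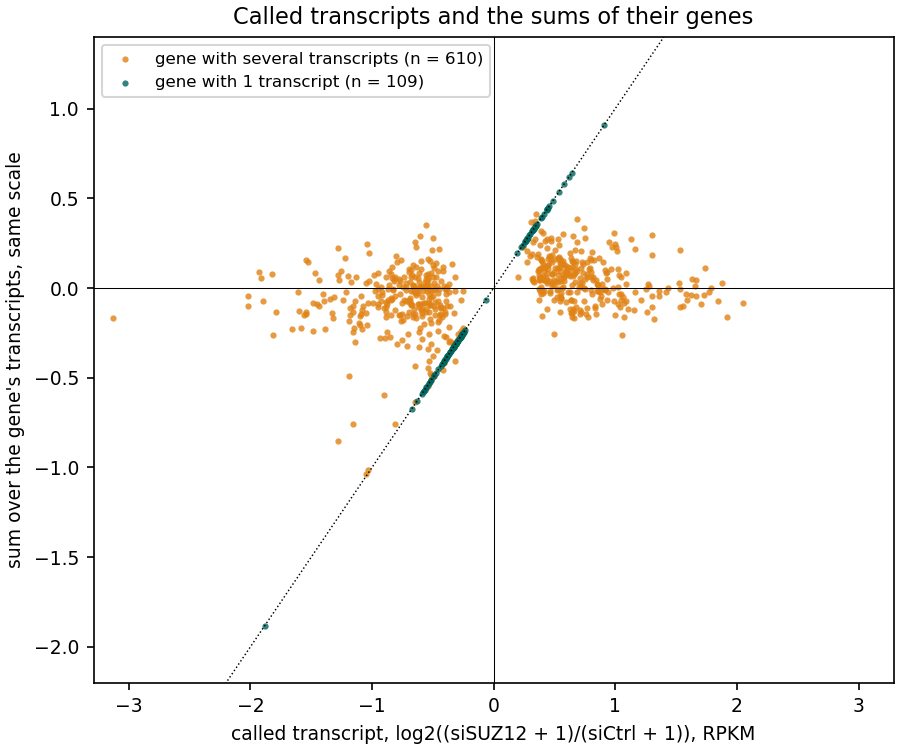
Called transcripts and the sums of their genes after SUZ12 knockdown. Each point is 1 called transcript, with its log2 fold (pseudocount 1, RPKM) on the horizontal axis and the log2 fold of the sum over its gene's transcripts on the vertical axis; 610 calls in genes with several transcripts lie mostly near 0 on the vertical axis, and 109 calls in genes with 1 transcript lie on the diagonal.

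At the level of whole genes few sums moved far. Of 8351 genes with at least 5 RPKM in both groups, 99.7% lay within 1.5-fold, with 17 lower and 5 higher by more; the genes named from these were chosen after their values were seen. After SUZ12, the lowest sums with a call were those of MOCS2 (a molybdopterin synthase; 39.8 to 18.9 RPKM, fold 0.475), CAPZB (an actin capping protein; 79.4 to 38.9, 0.489), PAIP1 (a partner of poly(A)-binding protein; 0.542) and CD164 (a sialomucin; 0.585), from the authors' deposited table. SUZ12P1, a pseudogene of SUZ12 whose reads are hard to assign because the sequences are alike, was called at 10.9 and 6.46 RPKM in the authors' deposited table. The 2 called genes with a higher sum were FSCN1 (an actin-bundling protein; 19.3 RPKM in siSUZ12, fold 1.61) and CALCB (a calcitonin-related peptide; 24.1 RPKM in siSUZ12, 1.52), from the authors' deposited table.

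**Figure D2:**
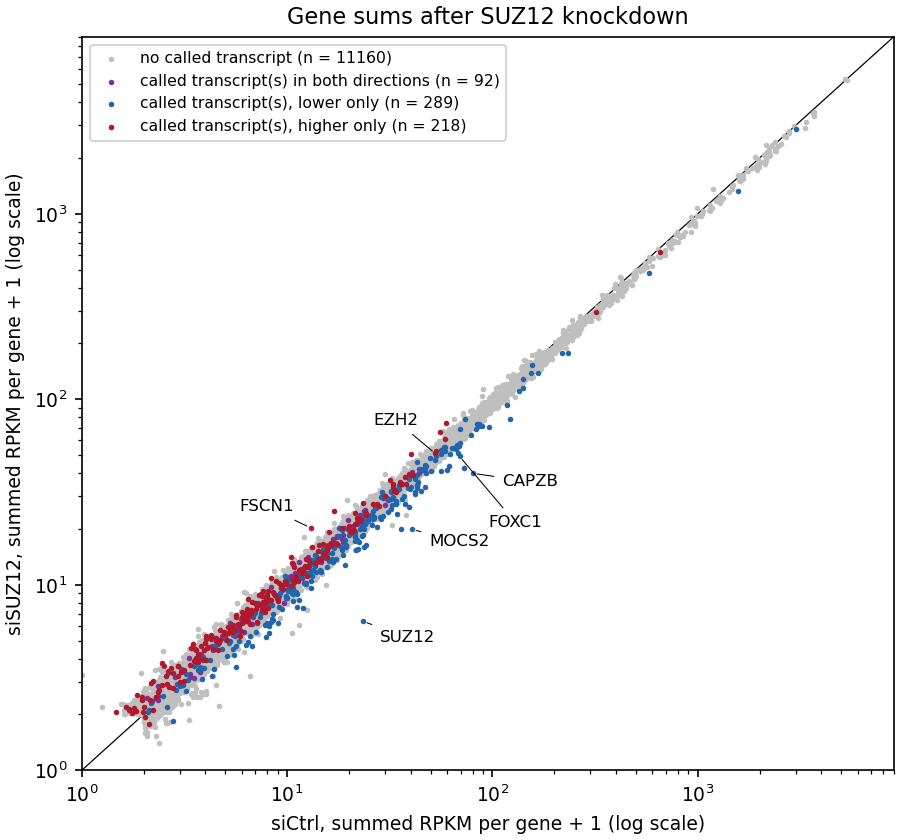
Summed RPKM per gene (plus 1, log axes) in siCtrl and siSUZ12 for the 11759 genes with at least 1 RPKM in either group, coloured by whether the authors called a transcript of the gene. SUZ12 lies far below the diagonal, and 99.7% of genes with at least 5 RPKM in both groups lie within 1.5-fold of equal.

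Developmental transcription factors outside the HOX clusters, a gene group that PRC2 is known to repress, had slightly higher gene sums after knockdown. Of 84 tested, 69 were higher and 15 lower, with a median log2 fold of 0.10. Calls were few in the authors' deposited table: TBX3, a T-box factor of limb and breast development, rose in its transcript NM_016569 from 6.17 to 8.37 RPKM (fold 1.36), while its gene sum was 11.3 and 12.7 RPKM. FOXC1, a forkhead factor of eye development, fell from 68.1 to 48.2 RPKM (0.708) in the authors' deposited table. MEIS2 NM_002399 was listed at 0 in siCtrl and 0.529 RPKM in siSUZ12 in the authors' deposited table, and PAX3, a neural crest factor, had calls in both directions, with gene sums of 0.984 and 1.08. ZIC2 (0.994) and DLX2 (1.14), the most expressed uncalled members, complete the named ones of the authors' deposited table.

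The HOX genes, which set position along the body axis, had 27 of 35 gene sums higher and 8 lower, with a median log2 fold of 0.06 and no call by Cuffdiff in the authors' deposited table; 3 of 42 transcripts lay below 0.05 in its column headed q-value. The most expressed were HOXB9 (87.6 RPKM in siCtrl, 94.3 in siSUZ12), HOXA10 (65.6 and 67.3), HOXA5 (60.7 and 56.9), HOXA9 (59.3 and 59.7) and HOXD13 (53.8 and 49.0), as sums from the authors' deposited table. The medians of the HOX list and of the developmental list were both at percentile 100 of 10000 random lists matched on expression. Genes of a random list need not move together as genes of a chosen list can, so these percentiles are not error rates. The share of called genes did not differ detectably from that of the other genes tested for either list (Fisher's exact test, two-sided, adjusted p = 0.576 for HOX and 1 for the developmental list).

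Extracellular matrix and adhesion genes were the 1 list of 17 whose share of called genes passed the test, with 6 of 27 tested genes called, 4 higher and 2 lower. LAMA4, a laminin chain, rose in its transcript NM_002290 from 0.340 to 1.68 RPKM (fold 4.95; gene sum 1.20), and ITGAV, an integrin chain, in NM_002210 (1.77), in the authors' deposited table, while the ITGAV gene sum had a fold of 0.905. ITGA6 NM_000210 (0.439, gene sum 0.860) and ITGB1 NM_133376 (0.752, gene sum 0.825), both integrin chains, fell in the authors' deposited table, and the uncalled VIM (vimentin) and LAMC1 stood at 0.967 and 1.07. The 22.2% of genes called compared with 5.06% of the other tested genes (Fisher's exact test, two-sided, p = 0.002, adjusted p = 0.0342 over 17 lists), and the list's median log2 fold of 0.09 was at percentile 99.9 of matched random lists. The adjusted p was 0.0647 without the RPKM minimum, 0.0696 with calls at an adjusted p under 0.01, 0.592 with an absolute log2 fold of at least 1 and 0.636 among genes with 1 transcript.

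Neuronal genes, another group under PRC2 control in many cell types, had 2 of 16 called, both higher. CNTNAP2, a neuronal adhesion protein, rose from 3.07 to 4.21 RPKM and NEFL, a neurofilament chain, from 12.2 to 15.0 in the authors' deposited table, and the uncalled UCHL1 and STMN3 stood at folds of 0.998 and 0.933. The median log2 fold of the list was 0.09, at percentile 99.6 of matched random lists, and at 79.7 without the RPKM minimum. Imprinted genes had no called member among 11 tested, with 1 of 19 transcripts below 0.05 in the column headed q-value of the authors' deposited table, a median of 0.11 and percentile 98.9 (93.2 without the minimum). IGF2, a growth factor, was called below the minimum in the authors' deposited table (0.331 to 0.695 RPKM), while GNAS (0.993) and PLAGL1 (1.06), in folds of gene sums, were uncalled. Germline genes had 2 tested and 0 called, with 1 transcript below 0.05 in that column of the authors' deposited table.

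PRC1, the other Polycomb complex, had 1 of 21 genes called: PCGF5, whose transcript NM_032373 fell to a fold of 0.264 in the authors' deposited table while another rose, with a gene sum of 1.07. The uncalled CBX6 (1.06) and BMI1 (1.18) were its most expressed members in the authors' deposited table, and the list's median of -0.04 was at percentile 34.3 (random median -0.03). The PRC2 core list, which holds SUZ12, had 2 of 5 genes called, a median of -0.13 and percentile 3.06 (random median -0.05), and the accessory list a median of -0.09 and percentile 3.72 (random median -0.02).

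Cell cycle genes had lower gene sums: 42 of 50 were lower and 8 higher, with a median log2 fold of -0.10 at percentile 0.48 of matched random lists. Genes of like expression were lower too, with a median of -0.07 in those random lists. MCM10 NM_182751 (fold 0.638, gene sum 0.965) and CDC6 (42.0 to 32.2 RPKM, 0.766), both needed to start DNA replication, fell in the authors' deposited table, and CCND1 (cyclin D1) rose from 2.42 to 3.56 RPKM, while PCNA and MCM7, with gene sums of 0.914 and 0.899, were uncalled. Among 8 CDK inhibitors, CDKN3 NM_005192, a phosphatase that acts on cyclin-dependent kinases, fell (0.728, gene sum 0.927) in the authors' deposited table. CDKN2A and CDKN2C, with gene sums of 1.09 and 1.04, were uncalled. Within CDKN2A, the authors' deposited table lists NM_058195 at 116 and 132 RPKM (fold 1.14), while NM_000077 stood at a fold of 1.00 from 46.0 RPKM in siCtrl. The median of the CDK inhibitor list, 0.09, was at percentile 99.4. Among 27 p53 targets, 3 had a transcript called lower and 1 a transcript called higher in the authors' deposited table: GADD45A NM_001199741 (0.359), BBC3 NM_001127241 (0.557) and FAS NM_152871 (0.415 RPKM, then listed at 0) were lower and ZMAT3 NM_152240 (1.82) was higher. Their gene sums had folds of 0.899 for GADD45A, 0.958 for BBC3, 1.14 for FAS and 1.16 for ZMAT3. The uncalled CCNG1 and BAX had gene sums of 0.928 and 0.908 in the authors' deposited table. The gene-sum median of the list was -0.07 (random median -0.02), at percentile 2.0, and at 3.48 with a minimum of 5 RPKM.

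Cholesterol synthesis genes had 2 of 20 called in the authors' deposited table, MVK NM_001114185 (mevalonate kinase; 3.73, gene sum 14.2 and 13.5 RPKM) higher and IDI1 (an isoprenoid isomerase; 0.827) lower, with FDPS (gene sum 0.851) uncalled and a median at percentile 21.4. The unfolded protein and integrated stress response list had 0 of 29 called by Cuffdiff in the authors' deposited table, with 5 of 53 transcripts below 0.05 in its column headed q-value, and a median at percentile 9.7. Interferon response genes had 0 of 13 called (percentile 29.6) and long non-coding RNAs 0 of 9 (percentile 13.5) in the authors' deposited table, with 0 transcripts below 0.05 in that column for either. Among 46 cytosolic ribosomal protein genes, whose reads can be shared with processed pseudogenes, RPLP2 fell from 1573 to 1328 RPKM in the authors' deposited table (0.844). RPS2 (0.996) and RPS18 (0.911) were uncalled in the authors' deposited table, and the median was at percentile 96.1. Of 13 housekeeping genes, EEF1A1, the translation elongation factor, was called lower at 0.956 in the authors' deposited table and TBP NM_001172085 was listed at 0 and 1.06 RPKM (gene sum 0.927). The EEF1A1 call rests on a small change (3006 to 2873 RPKM) with 0 in the column headed q-value of the authors' deposited table. GAPDH NM_002046, with a larger change (0.896), had 0.0892 in that column. GAPDH (gene sum 0.897) and TUBA1B (0.931) were uncalled in the authors' deposited table, and the median was at percentile 22.7. Markers of other cell types were scarcely expressed, with 1 fibroblast, 2 blood and 0 keratinocyte or liver genes reaching 1 RPKM, and 0 called in the authors' deposited table.

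By Benjamini-Hochberg over all transcripts tested, and adjusted over the list alone, the column headed q-value of the authors' deposited table passed 0.05 for 2 and 3 transcripts of the PRC2 core, 1 and 1 of the accessory subunits, 2 and 4 of PRC1, 0 and 0 of HOX and 4 and 5 of the developmental factors. In the authors' deposited table the same counts were 2 and 4 for neuronal genes, 1 and 2 for CDK inhibitors, 3 and 3 for the cell cycle, 3 and 7 for p53 targets and 3 and 5 for cholesterol synthesis. Extracellular matrix and adhesion genes had 6 and 10, ribosomal proteins 1 and 0, and housekeeping genes 2 and 2, again from the authors' deposited table. The germline, imprinted, interferon, stress response, non-coding RNA and other cell type lists had 0 and 0.

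The peak lists were compared to ask whether EZH2 sites carry an active mark. The EZH2 list held 46886 narrow peaks (median width 185 bp, 10.2 Mb in all) and the H3K4me2/3 list 24617 peaks (median width 310 bp, 11.3 Mb). The strongest EZH2 peaks by the authors' score, −log10 of the q-value, lay in the EZH2 gene itself, at hg19 chromosome 7 from 148514882 to 148515302 (603.72), 148510955 to 148511352 (512.27) and 148511890 to 148512233 (131.55). The others of the top 5 lay at RPPH1, the RNA subunit of ribonuclease P (chromosome 14, 20811205 to 20811617, 295.56), within 1 kb of PARP2, and at RMRP, the RNA subunit of ribonuclease MRP (chromosome 9, 35657677 to 35658046, 294.9). The 4 strongest H3K4me2/3 peaks lay at genes of translation or close to them: at MED22 and RPL7A (chromosome 9, 136214777 to 136216223, 278.89), EEF2 (chromosome 19, 3984016 to 3985539, 270.35), RPL29 (chromosome 3, 52028770 to 52029969, 263.61) and RPL41 (chromosome 12, 56509697 to 56511327, 258.68).

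Most EZH2 peaks were weak and lay away from H3K4me2/3 peaks. A score of at least 20 was reached by 78 EZH2 peaks and by 8269 H3K4me2/3 peaks. Of the EZH2 peaks, 1702 (3.63%, exact 95% interval 3.46 to 3.80) overlapped an H3K4me2/3 peak by at least 1 bp, 6.00 times the mean of 0.605% in 1000 random placements (p = 0.001, the smallest they can give). Moved by 20 to 100 kb to either side instead, an alternative chosen after the data were seen, the same peaks gave a chance share of 0.963% and a ratio of 3.77. The ratio was 10.0 for the upper 0.1 of EZH2 peaks by score and 3.67 with gaps of up to 1 kb allowed. Over 10 equal groups of EZH2 peaks by score the share did not rise steadily. It was 3.775% in the lowest group, 2.41% in the 8th and 6.29% in the highest. Of the H3K4me2/3 peaks, 1729 (7.02%, 6.71 to 7.35) overlapped an EZH2 peak, from 1.54% in the lowest of 10 equal groups by score to 17.2% in the highest.

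The EZH2 gene stood apart from other loci in its strong EZH2 peaks and in its peaks shared with the H3K4me2/3 list. Its locus (chromosome 7, 148504463 to 148581441) held 16 EZH2 peaks and 18 H3K4me2/3 peaks, and 12 of the 78 EZH2 peaks that reached a score of 20. Of its EZH2 peaks 11 (68.75%) overlapped an H3K4me2/3 peak, compared with 3.61% elsewhere. A source of EZH2 gene fragments in both libraries would also give shared peaks. This overlap therefore need not mean that bound EZH2 sites carry the active mark. The widest H3K4me2/3 peak of the locus, from 148580342 to 148581331 (score 33.85), overlapped no EZH2 peak. The most shared peaks in any other locus was 4, at ALCAM, a cell adhesion molecule, and at the zinc finger gene ZNF503 with its antisense RNA ZNF503-AS2, and each of the other loci with a peak of score 20 held 1 such peak. The loci of SUZ12, EED, RBBP4 and EZH1 held 3, 1, 5 and 1 EZH2 peaks, with highest scores of 21.67, 4.73, 10.3 and 4.71. EZH2 was named here by the peak rule, and ALCAM and ZNF503 after their values were seen.

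**Figure D3:**
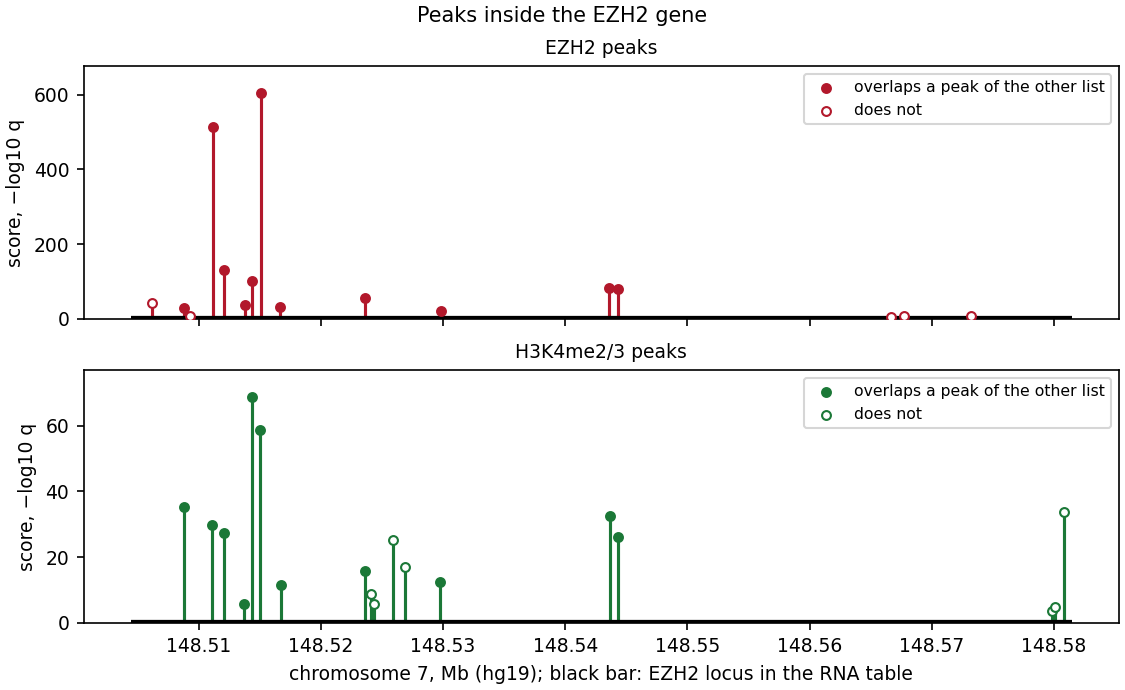
Peaks within the EZH2 gene on hg19 chromosome 7, at their positions in Mb, with the height of each line the authors' score (−log10 q) in the EZH2 list (upper panel) and the H3K4me2/3 list (lower panel). Filled points overlap a peak of the other list, as 11 of the 16 EZH2 peaks do; the black bar is the locus.

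Genes were then placed in classes by the peaks at their locus. Peaks of both kinds lay somewhere in the window of 8135 of 17757 genes (45.8%). Among these were the well expressed HOXB9, HOXA10, HOXA5 and HOXA9, while HOXD13 had H3K4me2/3 alone. Both peaks at a locus need not overlap: in all, 1702 EZH2 peaks overlapped an H3K4me2/3 peak. H3K4me2/3 alone was found at 3861 genes (21.7%), EZH2 alone at 2499 (14.1%), among them HOXD3 and HOXD4 (named after their values were seen), and neither at 3262 (18.4%). EZH2 peaks were thus at 59.9% of genes and H3K4me2/3 at 67.6%, and they met at the same genes more often than independent marks would (odds ratio 2.75, 95% interval 2.58 to 2.93, Fisher's exact test, two-sided, p = 2.1e-210). Loci with both were long, with a median of 58.7 kb compared with 11.0 kb for loci with neither, and pooled over deciles of locus length the odds ratio was 1.91. Any peak of a list counted, however weak. The median EZH2 score was 5.71, and the lower quartile of EZH2 peak width, 176 bp, equalled the minimum. Without an input library, 59.9% is a share of loci with a listed peak and not a measure of how many genes EZH2 occupies.

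Expression in siCtrl was compared between classes to ask whether EZH2 is found at expressed genes. Genes with both kinds of peak had a median of 9.25 RPKM, and 83.8% of them (exact 95% interval 83.0 to 84.6) reached 1 RPKM. Genes with H3K4me2/3 alone had a median of 12.3 RPKM and 87.8% (86.7 to 88.8). Genes with EZH2 alone had a median of 0.135 RPKM and 24.8% (23.1 to 26.6), close to the 0.122 RPKM and 23.8% (22.3 to 25.3) of genes with neither. The difference in median log2 expression was 0.02 between EZH2 alone and neither (p = 0.35), -0.37 between both and H3K4me2/3 alone, and 3.56 between H3K4me2/3 alone and neither (p = 1e-05 for each of the latter, the smallest that 100000 permutations can give; adjusted 1.5e-05 over 3 tests). With peaks counted within 1 kb of the locus ends alone, the difference between both and H3K4me2/3 alone turned to 0.22 (permutation p = 6e-05), and with 5 kb beside the locus it was -0.23. With the upper 0.5 of each list by score, EZH2 alone and neither differed by 0.08 (permutation p = 0.0047).

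The response to SUZ12 knockdown was compared between classes to ask whether genes with an EZH2 peak change more than genes of like expression without one. The called transcripts with an EZH2 peak at their locus and the largest folds in the authors' deposited table were those of CYREN, SNHG29, ZBTB22, CHEK2 and STXBP5 among the higher and CELF1, DCAF8, SUZ12, SCRN1 and ZNF48 among the lower. Of these SUZ12 is the siRNA target, and the gene sums of the others had folds between 0.868 (ZBTB22) and 1.06 (SCRN1). Of 661 tested genes with EZH2 alone, 442 had a higher gene sum (median log2 fold 0.06), compared with 431 of 813 genes with neither (median 0.01). Of 6875 genes with both, 40.3% were higher (median -0.03), compared with 34.0% of 3410 genes with H3K4me2/3 alone (median -0.04).

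Within deciles of expression, genes with EZH2 alone lay 0.04 above genes with neither on the log2 scale (p = 1e-04, the smallest that 10000 permutations can give; adjusted 0.0002 over 2 tests), and genes with both lay 0.01 above genes with H3K4me2/3 alone (permutation p = 0.0002, adjusted 0.0002). Without the RPKM minimum the difference for EZH2 alone was 0.0076 (permutation p = 1e-04). Calls were found at 4.84% of genes with EZH2 alone and 2.58% of genes with neither (odds ratio 1.92, Fisher's exact test, p = 0.0241, adjusted 0.0481 over 6 tests). They were found at 5.76% of genes with both and 4.40% with H3K4me2/3 alone (odds ratio 1.33, Fisher's exact test, p = 0.00374, adjusted 0.0112). Split by direction, higher calls were more frequent with both than with H3K4me2/3 alone (odds ratio 1.51, Fisher's exact test, adjusted p = 0.0112); lower calls (1.13, adjusted 0.332) and both directions for EZH2 alone (1.83 higher and 2.18 lower, adjusted 0.112 each) did not pass. The odds ratio for EZH2 alone was 1.39 (Fisher's exact test, p = 0.0919) with the upper 0.5 of each list by score, 1.69 (p = 0.323) among genes with 1 transcript and 1.51 (p = 0.366) with at least 5 RPKM. With peaks within 1 kb of the locus ends alone, none of the 4 undirected contrasts passed: the log2 differences were 0.011 (permutation p = 0.24) and 0.0021 (permutation p = 0.43), and the odds ratios 1.22 (Fisher's exact test, p = 0.379) and 0.843 (p = 0.124). Matched on expression and locus length, the excess in called share was 1.71 percentage points for EZH2 alone (p = 0.071) and 0.232 for both (p = 0.6), by permutation, while the log2 differences stayed past the threshold at 0.03 and 0.0064.

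**Figure D4:**
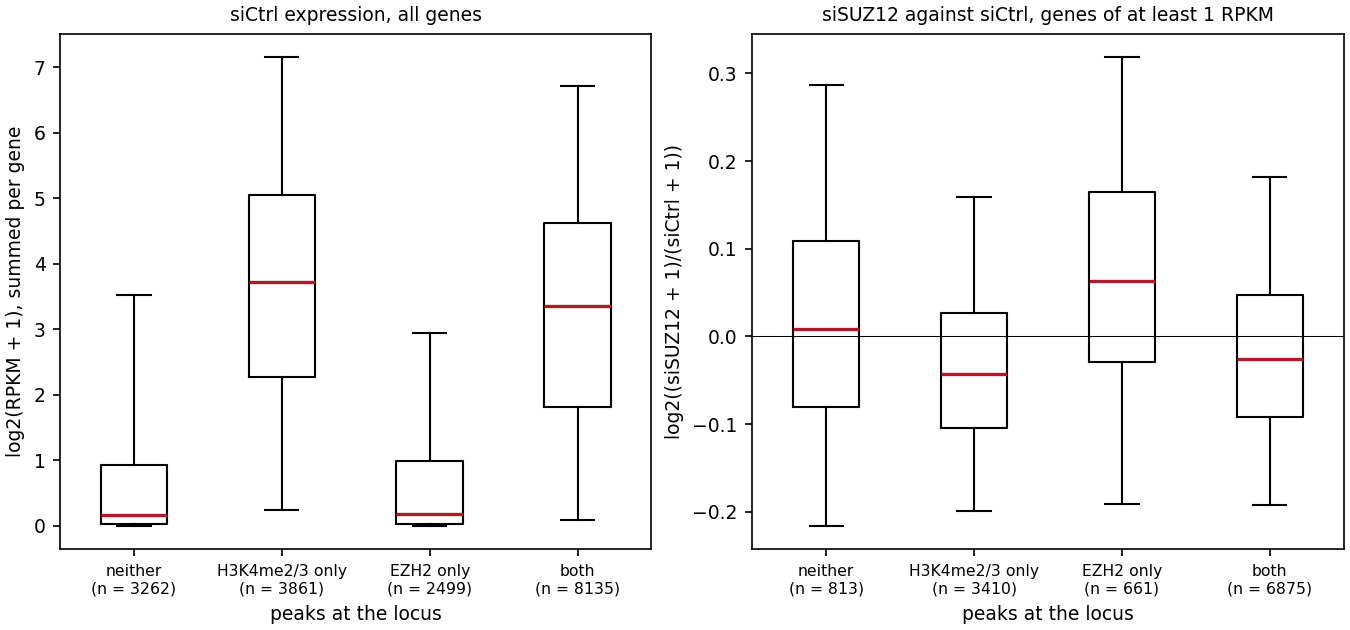
Left, siCtrl expression as log2(RPKM + 1) per gene, for 17757 genes by the peaks at their locus; right, log2 fold of gene sums (pseudocount 1) for the 11759 genes with at least 1 RPKM in either group. Boxes span the quartiles with the median in red and whiskers the central 90% of genes; medians of expression are high wherever H3K4me2/3 is present, and the highest median fold, 0.06, is that of EZH2 alone.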

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

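The count on the mitochondrial chromosome was chosen only after the peak lists had been seen. Outside the chromosomes of the genes compared, the EZH2 list holds 7 peaks on the mitochondrial chromosome, with scores from 10.83 to 21.72 over 4434 bp in all, and the H3K4me2/3 list holds 0 there. The result stands out because it lies in a part of the genome that belongs to no comparison of genes, and the other ChIP list has 0 peaks there. No explanation was tested for it.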

How the results depend on the processing

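The alternatives chosen only after the results were seen were genes with 1 transcript, the column headed q-value at face value, calls whose gene sum moved alike, calls without zeros, recomputed Benjamini-Hochberg, matching on locus length, local moves of peaks, peaks outside the EZH2 gene, loci with 1 gene, locus ends, and high against low EZH2 scores. No paired analysis was possible because the RNA table holds 1 value per group, which also ruled out leaving out a replicate and running another test tool. The count of 736 called transcripts (338 higher, 398 lower) was 292 (92 and 200, so 31.5% higher in place of 45.9%) with at least 5 RPKM, 417 (187 and 230) at an adjusted p under 0.01 and 134 (59 and 75) with an absolute log2 fold of at least 1, all of which are subsets by construction. It was 3107 (1455 and 1652) with the column headed q-value at face value, 109 (35 and 74) among genes with 1 transcript and 150 (47 and 103) where the gene sum moved the same way by 1.2-fold. SUZ12 stayed between -1.86 and -2.07 in log2. The extracellular matrix list, with an adjusted p of 0.0342, had 0.0647 without an RPKM minimum, 0.0696 at an adjusted p under 0.01, 0.592 with an absolute log2 fold of at least 1 and 0.636 among genes with 1 transcript, so that 0 lists passed there, and 0.0243 at 5 RPKM; the cause was not tested. The HOX and developmental lists stayed at percentile 100 in each setting run. The overlap of the peak sets and the association of both marks over genes kept their direction and side of the threshold in each alternative run, though the ratio to chance of 6.00 was 10.0 for the upper 0.1 of EZH2 peaks by score, 3.67 with gaps of up to 1 kb and 3.77 with local moves. The difference in siCtrl expression between EZH2 alone and neither was 0.0754 (permutation p = 0.0047) with the upper 0.5 of each list by score, and that between both and H3K4me2/3 alone turned to 0.22 (p = 6e-05) at locus ends. The response of EZH2 alone against neither, 0.04 in log2, was 0.0076 (permutation p = 1e-04) without an RPKM minimum and 0.011 in log2 (permutation p = 0.24) at locus ends; its odds ratio of a call was 1.39 (p = 0.0919) with the upper 0.5 by score, 1.22 (p = 0.379) at locus ends, 1.69 (p = 0.323) among genes with 1 transcript and 1.51 (p = 0.366) with at least 5 RPKM, and its excess in called share was 1.71 points (p = 0.071) matched on locus length, from 2.37 (p = 0.015) without. The response of both against H3K4me2/3 alone was 0.0021 in log2 (permutation p = 0.43) and turned to an odds ratio of 0.843 (p = 0.124) at locus ends, and its excess in called share was 0.232 points (p = 0.6) matched on locus length, from 1.20 (p = 0.012) without; the cause was not tested for any of these. Among genes with an EZH2 peak, those with peaks in the upper 0.5 by score lay 0.01 higher in log2 (permutation p = 0.0007), and 0.0058 (p = 0.06) matched on locus length. Of the alternatives of the results named in the plan, 112 kept their direction and side of the threshold or, for counts, stayed within 1.5 times (among them settings that cannot move a result, such as the pseudocount for counts of the authors' calls), and 13 of these 112 nevertheless moved in value by over 1.5 times, while 22 counts moved by over 1.5 times, 12 lost the threshold, 1 gained it and 2 turned direction. With depth unknown and no values per replicate, the precision of single transcripts could not be given.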

Other observations

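The tests chosen only after the results were seen are the shares of list genes with a peak, the 3 tests on the EZH2 gene, the tests of gene sums and of low RPKM for called transcripts, and the joining of the HOX and developmental lists.

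EZH2 peaks were unevenly spread over the gene lists. Genes of the unfolded protein and integrated stress response had an EZH2 peak at 75.9% of 29 loci, compared with a median of 48.3% in random lists matched on locus length (percentile 99.95), and each of their loci had an H3K4me2/3 peak. Cell cycle genes had 74% (random 56%, percentile 99.5) and ribosomal protein genes 58.7% (random 34.8%, percentile 99.9), again with H3K4me2/3 at each locus. The HOX genes had 56.4% (random 35.9%, percentile 99.7) and the developmental transcription factors 57.3% (random 44.4%, percentile 99.9), with H3K4me2/3 at 71.8% and 60.5% of loci. Interferon response genes stood at the other end, with an EZH2 peak at 21.9% (random 50%, percentile 0.055) and an H3K4me2/3 peak at 28.1% of 32 loci. The random lists were not matched on expression.

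All 4 HOX clusters held peaks of both kinds. The HOXA cluster held 8 EZH2 peaks and 40 H3K4me2/3 peaks over 107 kb, HOXB 15 and 17 over 199 kb, HOXC 11 and 20 over 121 kb, and HOXD 7 and 11 over 98.1 kb. The highest EZH2 scores were 12.29 in HOXA, 9.53 in HOXB, 10.07 in HOXC and 6.73 in HOXD, while the highest H3K4me2/3 scores were 79.93, 113.09, 33.63 and 61.06. Among uncalled developmental genes, named after their values were seen, FOXF1 had a gene-sum fold of 1.33, HOXD3 1.31 and TWIST1 1.25, from the authors' deposited table.

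The strong EZH2 peaks inside the EZH2 gene may come from a source of EZH2 gene fragments present in both ChIP libraries, such as a plasmid or cDNA. Such a source would place the same peaks in both lists, and 91.67% of the gene's EZH2 peaks of score 20 or more overlapped an H3K4me2/3 peak, but this overlap is the observation that prompted the idea and does not test it independently. A copy number gain reaching beyond the gene would raise scores in its flanks as well. In the 250 kb on either side lay 0 EZH2 peaks of that score, and the highest score among 23 peaks there was 13.84. Inside the gene 12 EZH2 peaks reached that score, the highest at 603.72. Only 78 of all 46886 EZH2 peaks reached that score, so 0 in the flanks would be likely without a gain. These values argue against a gain reaching beyond the gene as the source of its strong peaks. A gain within the gene alone was not tested. EZH2 protein bound to its own gene, with 68.75% of all the gene's EZH2 peaks also in the H3K4me2/3 list, cannot be told apart from a shared source of fragments, because no input library or EZH2-depleted ChIP was analysed here. Exon positions in hg19, which would separate cDNA from genomic DNA, were not used here.

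Called transcripts whose gene sum hardly moved, as for PSRC1 and CELF1, may reflect how reads were divided between the transcripts of a gene by the authors' estimate. The median absolute log2 fold of the gene sum was lower by 0.24 for called genes with several transcripts than for called genes with 1. With 1 transcript the sum is the called transcript itself, so the choice of calls alone gives part of this gap. A true change in transcript choice would also give it, which leaves the division open. Low expression of the called transcripts stays open too. Of calls with at least 1 RPKM in both groups, 87.04% (282 of 324, exact 95% interval 82.9 to 90.5) had a gene sum within 1.2-fold. With at least 5 RPKM in both it was 73.0% (81 of 111). The interval counts calls of the same gene, which share a sum, as separate. The pattern was thus not confined to low transcripts, but a steady sum is the pattern itself and does not test its cause. Of the 548 calls with a gene sum within 1.2-fold, 48.54% lay under 1 RPKM in at least 1 group and 19.7% in both. An altered choice of transcript after SUZ12 knockdown stays open: 93 genes had calls in both directions, and it cannot be told apart from the division of reads without values per replicate.

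The slightly higher sums of developmental transcription factors and HOX genes had a joint median log2 fold of 0.09 over 119 genes. Short loci or low expression, as matched in bins, did not account for this median. The joint list was at percentile 100 of random lists matched on both, whose highest median among 10000 was 0.04. That percentile is not an error rate, since genes of a chosen list can move together. Release of PRC2 from genes with an EZH2 peak could raise the sums, and members with such a peak would then be the higher ones. Pooled over loci with and without the active mark, the values went the other way. The 71 members with an EZH2 peak had a median of 0.07 and the 48 without 0.09. The difference of -0.022 (permutation p = 0.37) is within its spread and leaves the release open. Medians were not compared separately by the active mark. Without that mark, log2 folds ran from -0.05 (SOX18) to 0.39 (LHX2) with an EZH2 peak and from -0.14 (HOXA4) to 0.27 (BARX1) without. With that mark, they ran from -0.49 (FOXC1) to 0.325 (MSX2) with an EZH2 peak and from -0.16 (POU3F3) to 0.331 (HAND1) without. Other differences between the siRNA pools were not tested. Both lists were fixed before the data were examined, and they were joined after the median of each had been seen.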
